A study of Mus musculus with 10 samples.

How the data were processed

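Dimethylation of histone H3 at lysine 4 (H3K4me2), a mark of promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing in mouse lymphocytes. Per the labels' protocols, the cells were sorted from mice with airway inflammation that carry a fluorescent reporter of Gata3, and libraries were made with a Nextera transposase protocol. Cells labelled as naive T cells, T helper 2 (Th2) cells and group 2 innate lymphoid cells (ILC2s) each gave 2 libraries, the first from bronchoalveolar lavage and the second from the mediastinal lymph node. The labels do not give the sort gate behind the name naive T, so a count for naive T cells is one for cells sorted under that label. The sample descriptions hold the codes gneg and gpos, whose meaning is not stated. CD4+ cells of the spleen and of the thymus gave 1 library each. The labels list 2 further samples of immunoglobulin G (IgG) precipitation whose own files were not used here; their reads enter only as the background of the peak finder. The labels give these 2 samples the H3K4me2 antibody although their titles say IgG, which leaves open what the required excess over background means. Because the 2 libraries of a cell type come from different sites, the spread between them holds the site, any difference between animals and any technical difference. The limma p-values without a block are set against that spread. The labels do not say whether libraries came from the same or from separate animals, and the series design speaks of biological replicates. Those p-values therefore compare a difference only with the spread between these samples.

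Per the submitters' processing notes, the authors used Bowtie, HOMER and the mm10 mouse genome, with no versions given. Per the file headers, peaks were called separately in each library with HOMER findPeaks, with an initial peak size of 1000 bp and a minimum distance of 2500 bp, and neighbouring peaks were stitched into regions of variable length. The headers also give a false discovery rate of 0.001, a required 4-fold excess over IgG, and a tag minimum set in the command of each library. That minimum came to between 39.9 and 40.4 tags per 10000000 sequenced tags in all 8 libraries, so the lists share 1 threshold per tag sequenced. The IgG background was the thymus library for all lists except that of spleen CD4+ cells, per the file headers. The deposited signal of each peak is a normalized tag count, the number of tags in the peak scaled by the authors to 10000000 tags in the library. The deposited lists also give a findPeaks score, a fold change (ratio) of tags over IgG, and a Poisson p-value against IgG, all made by the authors' peak finder. The score only served to rank peaks within a list, and it followed the normalized tag count weakly, with Spearman correlations across peaks of 0.15 to 0.2. Between 1.1% and 3.6% of the peaks of a list lay slightly under the stated minimum, the lowest at 34.5 tags. Absence from a list means that a region did not meet the tag minimum or the other criteria, among them the excess over IgG, and not that it lacks signal.

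Depth differed between libraries. The headers give total tags of 23926669 for naive T cells of the lavage, 24614614 for those of the lymph node, 16041895 and 11870820 for Th2 cells, 24945548 and 22830388 for ILC2s, 21451958 for spleen and 19036573 for thymus CD4+ cells. The authors' approximate immunoprecipitation efficiency, the share of tags in peaks, was 37.3% and 53.7% for naive T cells, 28.7% and 29.3% for Th2 cells, 43.2% and 45.0% for ILC2s, 44.2% for spleen and 53.3% for thymus. A lower efficiency leaves fewer regions above a common threshold, so counts of regions were also computed with equal numbers of peaks from every library.

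Peaks of the 6 libraries of naive T, Th2 and ILC2 cells were merged where they lay within 500 bp, giving 27854 regions with a median length of 2545 bp. A region was counted as differing between 2 cell types when both libraries of one had a peak in it and neither library of the other did. The count was set beside those of the other ways to part the same 4 libraries into 2 and 2, which are too few for a p-value. Similarity of libraries was the Jaccard index of the base pairs under their peaks, with an exact one-sided permutation over the 15 ways to pair the 6 libraries, or over the 10 ways to part them into 3 and 3 for the site.

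Genes came from a RefSeq table of the GRCm38.p6 assembly, which has the coordinates of mm10 and gives no strand and no exons. The planned assignment to the nearest transcription start site was therefore replaced by the nearest protein-coding or receptor constant gene interval within 100 kb, and introns, exons and untranslated regions were not told apart. Of the regions, 26622 (95.6%) had such a gene, and 73.6% overlapped one. Nearest means position only, since an enhancer can act on a gene farther away. The planned motif comparison was not run, as no genome sequence was used here.

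Before the data were examined, 19 gene lists, the tests, the alternatives and a rule for named genes were fixed. For each list, regions called only in the first cell type minus those called only in the second were divided by all regions assigned to the list. That share was compared, two-sided, with 10000 random lists matched on regions per gene, and p was adjusted over the 57 list tests by the Benjamini-Hochberg method. These p-values describe the libraries at hand, since genes are not replicates. Of each list, up to 4 members with the largest difference in regions could be named. The rule also took the 10 genes with most regions on either side of each comparison (of lavage against lymph node as well), the 5 regions with the smallest adjusted p in each direction of the height test, and Gata3, Il5, Il13, Il4, Rora, Il1rl1, Cd3e, Tbx21, Foxp3 and Actb throughout. Items named outside it are said to be chosen after their values were seen.

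Peak height was compared at the 11669 regions with a peak in all 6 libraries. The log2 of the normalized tag count of the highest peak, with 1 added, was centred on each library's median and fitted with limma (version 3.58.1, R 4.3.3) with a mean-variance trend, and calls used an adjusted p of 0.05. Centring removed shifts between -0.37 and 0.49 on the log2 scale. Since stitched peaks differ in length, a taller value can reflect a wider peak as well as a denser one. The spread of a region was estimated over all 3 cell types together, so the naive T pair enters it in every comparison, also that of ILC2s with Th2 cells. No count model was used, because the deposited values are scaled. Other work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

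Region presence, the list test and the height test were tried on simulated data, and the similarity permutations were not. All 200 of 200 planted ILC2 regions were recovered among 27854 simulated regions. They were placed in both ILC2 lists and in no other, so this checks only that the rule runs as stated. It does not measure how many real regions are missed. In simulated heights of 11669 regions for ILC2s against naive T cells, limma recovered 30.0% of regions raised by 1 on the log2 scale, 60.0% of those raised by 2 and 77.5% of those raised by 3, with 6 unchanged regions called. Of regions lowered by 1 it recovered 45.0%, and of those lowered by 2, 82.5%. All 6 libraries of a simulated region had the same spread, drawn at random from the fitted ones. These rates therefore do not cover a cell type whose 2 libraries differ more than the others. Of 300 random gene lists without planted regions, 3.7% had p under 0.05. Alternatives covered the peak threshold, the merging distance, the distance to genes, the scaling of heights, the pseudocount, each library left out in turn, and the replicate number as a block. Equal numbers of peaks ranked by normalized tag count or by tags per kb, and heights as tags per kb, were added after the data had been seen.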

Results

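The 8 H3K4me2 peak lists held between 14723 and 21985 peaks each. The naive T cell libraries had 16725 peaks in the lavage and 21985 in the lymph node, the Th2 libraries 14773 and 14723, and the ILC2 libraries 21380 and 21394. Spleen CD4+ cells had 20418 peaks and thymus CD4+ cells 20723. Each of the 3 airway cell types had n = 2 libraries, 1 per site, and spleen and thymus had no replicate. The series title names ILC2s in allergic airway inflammation, and the comparisons ask how the H3K4me2 landscape of these innate cells differs from that of Th2 cells and of the cells labelled naive T, and whether the site matters. Coordinates are of mm10. A value listed as 2 numbers gives the lavage library first.

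The ILC2 libraries shared most with each other, as did the Th2 libraries, and the naive T cell libraries did not. The Jaccard index was 0.834 for the ILC2 pair and 0.782 for the Th2 pair. It was 0.613 for the naive T pair, below the 0.740 and 0.704 that the naive T library of the lavage reached with the Th2 libraries. The lymph node naive T library instead shared most with spleen CD4+ cells (0.845). Pairs of the same cell type averaged 0.743 and other pairs 0.595, a difference of 0.147 (exact one-sided permutation p = 0.067, the smallest that 15 pairings allow). The difference was 0.249 without the lavage naive T library, 0.097 without the lavage ILC2 library and 0.094 without that of the lymph node. Pairs from the same site averaged 0.043 less than other pairs, a difference of -0.043 (exact one-sided permutation p = 0.7, with a smallest possible p of 0.1). No same-site pair is of the same cell type, while the other pairs include the same-type pairs. This difference therefore does not isolate the site. Of the 27854 merged regions, 11669 (41.9%) were called in all 6 libraries.

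**Figure D1:**
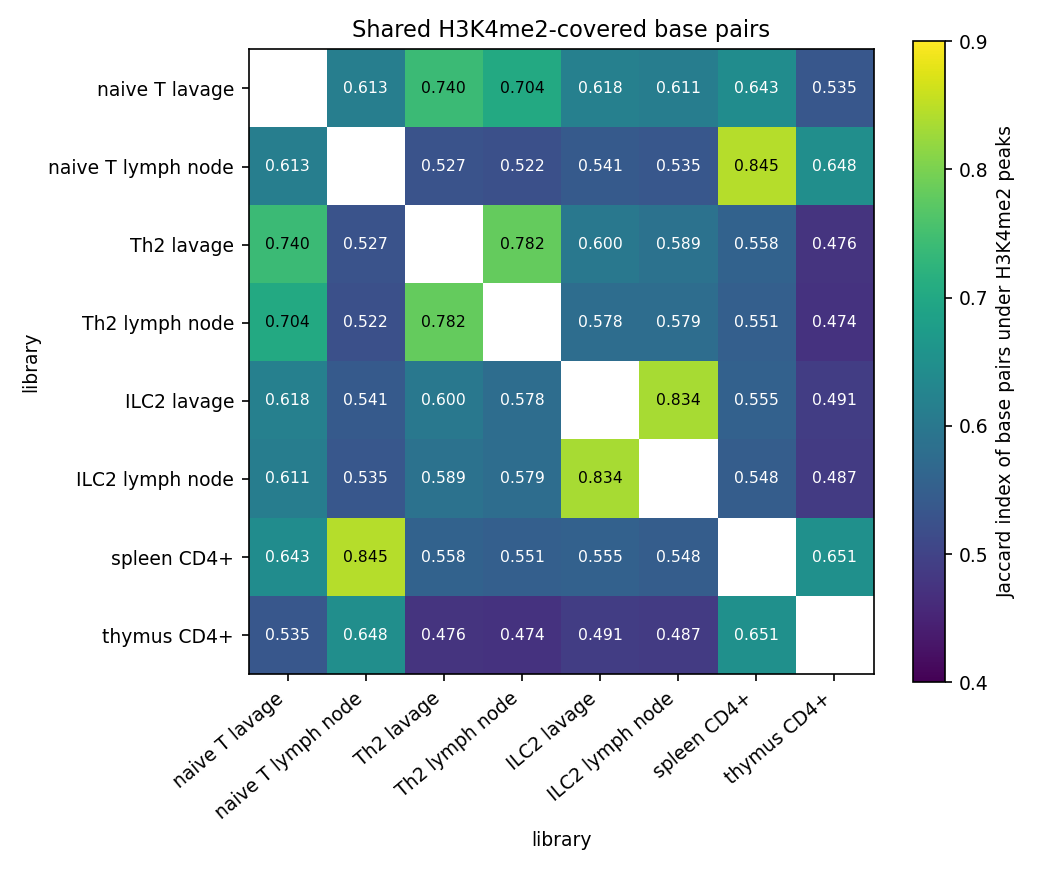
Jaccard index of base pairs under H3K4me2 peaks for every pair of the 8 libraries, with colour and printed number giving the index and the diagonal left blank. The ILC2 pair stands at 0.834 and the Th2 pair at 0.782, while the naive T pair stands at 0.613.

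ILC2s had H3K4me2 regions without a called peak in naive T cells near genes of the type 2 cytokine and ILC2 identity lists. On the cytokine list most lay near Il6, Csf2 and Ccl1, and none was assigned to Il4, Il5 or Il13. Near T cell receptor genes, ILC2s had fewer called regions than naive T cells. In all, 3222 regions were called only in ILC2s and 817 only in naive T cells. The regions near Il6, a cytokine gene, included 6 called only in ILC2s, and those near Csf2, which encodes the growth factor GM-CSF, included 4. Ccl1, a chemokine gene, had 3 and Il9, a type 2 cytokine gene, had 2. Rora, which encodes a transcription factor needed for ILC2 development, had 8 such regions, the receptor tyrosine kinase gene Kit had 6 and Tox had 5, with 1 called only in naive T cells. Arg1, the arginase gene, had 2, of which the taller lay 22947 bp outside the gene (chromosome 10, 24950417 to 24961204) and reached 908.8 and 1107.7 normalized tags.

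Of the 31 regions near type 2 cytokine genes, 16 were called only in ILC2s and 0 only in naive T cells, a balance of 51.6% against 8.8% in matched random lists (adjusted p = 0.0038 by permutation of lists). By gene, 5 of the 11 list members with a region had more ILC2 regions, 0 had fewer and 6 were level. Il4, Il5 and Il13 were among the level genes, with 1 region each. The ILC2 identity list had 31 against 2 of its 111 regions (adjusted p = 0.042), with 11 genes higher, 1 lower and 11 level. The lists that leaned to naive T cells were those of T cell, naive and follicular helper genes. T cell receptor and identity genes had 1 region only in ILC2s and 15 only in naive T cells among 61 (adjusted p = 0.0038), with 9 of 20 genes lower, 1 higher and 10 level. Naive and central T cell genes had 2 against 17 of 149 (adjusted p = 0.02), and follicular helper genes had 0 against 5 of 28 (adjusted p = 0.034). Among these genes, Themis, Lat and Cd40lg, all active in T cell signalling or help, had 3, 3 and 2 regions called only in naive T cells. Cxcr5, the follicle-homing receptor gene, also had 3, and Foxo1 3. The ILC2 identity call was lost without the naive T library of the lymph node (adjusted p = 0.21), the lavage ILC2 library (0.056) or the lymph node ILC2 library (0.16), and the follicular helper call without the naive T library of the lavage (0.18) or the same ILC2 libraries (0.056 and 0.059).

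No other list passed the threshold in this comparison. Regions only in ILC2s against only in naive T cells numbered 10 and 1 for Th17 and ILC3 genes, where Il17a and Ahr had 3 ILC2 regions each, and 12 and 1 for Th2 identity genes. They numbered 4 and 8 for regulatory T cell genes, 9 and 7 for Th1 and cytotoxic genes, 13 and 6 for asthma loci, 3 and 4 for residency and migration genes, 3 and 0 for neighbours of the type 2 locus and 7 and 0 for activation genes. Lists of other cell types gave 3 and 0 (B cell), 1 and 0 (macrophage and neutrophil), 2 and 0 (eosinophil and mast cell), 2 and 0 (natural killer cell) and 0 and 0 (airway epithelium). Housekeeping genes gave 4 and 0. The genes with most ILC2 regions were Itpr1 with 11 and Plcb4 with 9, which act in calcium and phospholipid signalling, while Il21r had a difference of -4.

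The 2 sets of ILC2 and naive T regions outnumbered the other ways to part the 4 libraries, which gave at most 303 regions (861 with equal numbers by score and 929 with the upper part of each list by score, where 961 were called only in naive T cells). The split depended on how many peaks entered: with equal numbers of peaks from every library, ranked by normalized tag count, 1529 regions were called only in ILC2s and 1079 only in naive T cells, which moved the ILC2 share from 79.8% to 58.6%. Without the lavage naive T library 4984 regions were called only in naive T cells. Without that of the lymph node there were 1368, where the ILC2 side came to 5039. Such counts can only rise when fewer libraries must match, so they do not show how far the naive T side rested on either library. Over all comparisons 11 list tests passed the threshold, against 1 with equal numbers by score, 0 with the upper part of each list by score, 5 with equal numbers by normalized tag count and 3 with genes within 10 kb. With every gene within 50 kb counted 13 passed, which kept 9 of the 11.

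**Figure D2:**
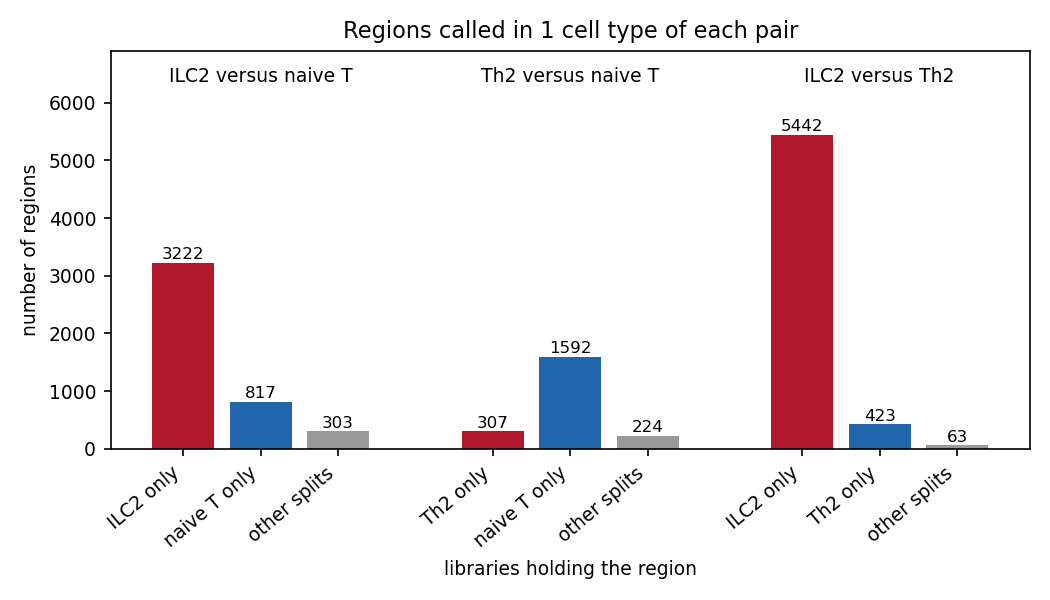
Number of merged regions with a peak in both libraries of one cell type and neither of the other, for each pair of cell types. Grey bars give the highest count from the other ways to part the same 4 libraries, which reached 303, 224 and 63.

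At regions called in every library, ILC2 peaks were higher than naive T peaks at 330 regions and lower at 196 of 11669 (limma, adjusted p under the threshold). The increase with the smallest p lay at Chdh (chromosome 14, 30003546 to 30030418), with 2250.5 and 2339 normalized tags in ILC2s and 154.2 and 248.6 in naive T cells (log2 fold change 3.72, SE 0.15, limma adjusted p = 0.0023). This region also lies within 50 kb of Il17rb, the IL-25 receptor gene, which was chosen after the values were seen. Increases nearest to Ikzf1 (2.68), Mgat5 (3.16), Gm5148 (2.59) and Notch2 (3.06) had the same adjusted p. The Ikzf1 region lay 13219 bp and the Gm5148 region 33162 bp outside the gene. The 5 decreases with the smallest p had Cd3d, Thy1, Cd3e, Arhgef10 and Zc3h12d as nearest genes, with log2 fold changes between -2.97 and -3.99 at that adjusted p. The Thy1 region lay 18315 bp outside the gene. Cd3e, a subunit of the T cell receptor complex, had 660.8 and 842.2 tags in naive T cells and 65.7 and 78.8 in ILC2s.

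Gata3, the transcription factor gene shared by Th2 cells and ILC2s, was covered by 1 region of 35135 bp (chromosome 2, 9862117 to 9897252). It was higher in ILC2s than in naive T cells (log2 fold change 1.20, SE 0.21, limma adjusted p = 0.043, or 0.083 with the replicate block). The labels do not give the naive T sort gate, so a sort on the Gata3 reporter, which could bear on this difference, was not told apart. The region beside Il5 (chromosome 11, 53731316 to 53737779) held 369.6 and 424.9 tags in ILC2s against 79.8 and 46.7 in naive T cells (2.86, SE 0.38, limma adjusted p = 0.02). At the tallest Rora region, which spans 65817 bp, ILC2s had 5787.8 and 5902.2 tags and naive T cells 1304 and 333.1, which did not pass the threshold (3.33, SE 0.75, limma adjusted p = 0.081), while the Rora region at 69027804 did (1.43, SE 0.16, limma adjusted p = 0.012; -0.08 with tags per kb). The 3 Actb regions did not pass, with log2 fold changes between -0.32 and -0.69.

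In the lists, 3 of 4 tested regions of type 2 cytokine genes were higher in ILC2s and 0 lower, both over all regions and adjusted over the list alone. ILC2 identity regions went both ways, with 7 of 28 higher and 5 lower over all regions and 12 and 5 adjusted over the list alone. Of 21 T cell receptor and identity regions, 9 were lower over all regions and 11 adjusted over the list alone, with 0 higher. Of 41 naive and central T cell regions, 8 were lower over all regions and 20 adjusted over the list alone, where 1 was higher. Height calls fell to few or none with either ILC2 library left out, fell less with either Th2 library left out, and rose with either naive T library left out. Without an ILC2 library the naive T and Th2 pairs alone set the shared spread. The loss of calls therefore does not show that they rest on 1 ILC2 library. With tags per kb the counts were 53 higher and 23 lower. Without centring they were 283 and 244.

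**Figure D3:**
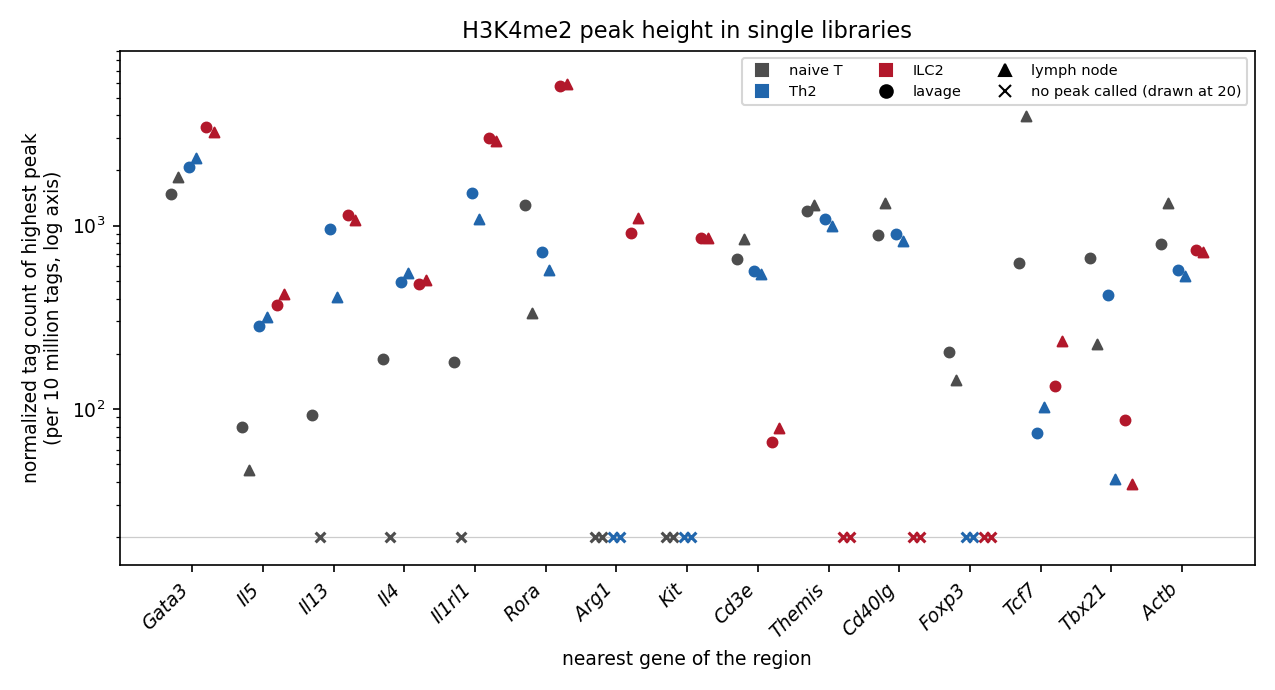
Normalized tag count of the highest peak (per 10000000 tags, log axis) in the tallest region of 15 named genes, with colour for the cell type, circles for lavage, triangles for lymph node and crosses at 20 for libraries with no peak called. Arg1 and Kit have peaks in both ILC2 libraries alone, Themis and Cd40lg in the T cell libraries alone, and Foxp3 in the naive T libraries alone.

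Relative to matched lists, the type 2 cytokine and Th2 identity lists leaned to Th2 cells against naive T cells. On the cytokine list this rested on Il6 and Ccl1, and no such region was assigned to Il4, Il5 or Il13. More regions in all were called only in naive T cells. In total 307 regions were called only in Th2 cells and 1592 only in naive T cells. Il1rl1, the IL-33 receptor gene, had 1 region called only in Th2 cells, and its tallest region (chromosome 1, 40422920 to 40448385) held 1512.3 and 1089.2 tags in Th2 cells, 181.4 in lavage naive T cells and no peak in those of the lymph node. Il6, Ccl1 and the lipid-sensing factor gene Pparg had 2 Th2 regions each, and Nfkb1, Foxp1 and Epas1 3 each. On the naive side, Tcf7 and Foxo1, transcription factor genes of resting T cells, had 3 regions each, although their list did not pass its test, and the Th1-associated genes Runx3 and Il12rb2 had 2 each. Foxp3, which defines regulatory T cells, had 1 region, with 203.5 and 144.6 tags in naive T cells and no peak in Th2 cells or ILC2s.

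Type 2 cytokine genes had 4 regions only in Th2 cells and 1 only in naive T cells among 31 (adjusted p = 0.042 by permutation of lists). By gene, 2 of the 11 members with a region were higher (Il6 and Ccl1), 1 was lower (Lif) and 8 were level, among them Il4, Il5 and Il13. Th2 identity genes had 6 and 2 among 47 (adjusted p = 0.033). The naive and central T cell list had 3 and 10 among 149 and did not pass (adjusted p = 0.55), nor did Th1 and cytotoxic genes with 2 and 10 of 73 (adjusted p = 0.24) or activation genes with 4 and 1 of 57 (adjusted p = 0.06). The type 2 call was lost without the lymph node Th2 library (adjusted p = 0.08) or the lavage ILC2 library (0.054), and the Th2 identity call without the lymph node naive T library (0.086) or either Th2 library (0.13 each). The genes with the largest excess of naive T regions were Znrf2 with a difference of -5 and Ext1, Rgs3 and Xylt1 with -4 each, and Itpr1 led the Th2 side with 4.

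The other splits of these 4 libraries gave at most 224 regions, or 750 with the upper part of each list by score, where the Th2 side had 751. With equal numbers of peaks by normalized tag count the split became 636 only in Th2 cells and 522 only in naive T cells, the Th2 share moving from 16.2% to 54.9%. The Th2 libraries had the lowest immunoprecipitation efficiency, 28.7% and 29.3%. Leaving out the lavage naive T library gave 992 and 7757 regions, under which Foxp1 turned from 3 to -7, and the Th2 side came to 640 without the Th2 library of the lavage and 483 without that of the lymph node. At common regions, limma called 17 higher in Th2 cells and 0 lower, with 2099 regions at an unadjusted p under 0.05. Without centring there were 32 higher and 220 lower. Over all regions 0 of 4 type 2 cytokine regions, 1 of 9 neighbours of the locus and 0 of 33 activation regions were higher, and 2, 4 and 3 adjusted over the list alone. Of 14 Th2 identity regions 0 were higher, over all regions and adjusted over the list alone. The calls numbered 0 with the replicate block, 0 with either Th2 or either ILC2 library left out, 59 and 6 without the lymph node naive T library and 1673 and 1052 without that of the lavage.

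The smallest p of the 17 was at a region of 22024 bp with no gene within 100 kb (chromosome 2, 9573936 to 9595960), whose next gene, 261 kb away, was Gata3. It held 1029.8 and 1309.1 tags in Th2 cells, 134.2 and 163.3 in naive T cells and 93.0 and 110.8 in ILC2s (Th2 against naive T: log2 fold change 3.57, SE 0.16, limma adjusted p = 0.017; 0.083 with the replicate block). Ptpn13 (3.52), Rhbdf2 (1.96), 4932438H23Rik (2.31) and Aff4 (2.13) followed at a limma adjusted p of 0.028 (0.1 with the replicate block). With tags per kb, the values of Rhbdf2 and 4932438H23Rik were -0.19 and -0.04. The region beside Il5 did not pass (2.88, SE 0.38, limma adjusted p = 0.073), nor did Gata3 (1.03, SE 0.21, limma adjusted p = 0.14).

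At the type 2 cytokine locus on chromosome 11, Th2 cells and ILC2s had peaks over Il4, Il13 and Rad50 that were low or not called in naive T cells. The Il13 region (53622351 to 53639942) had 961.2 and 407.7 tags in Th2 cells, 1140.9 and 1071.8 in ILC2s and 92.8 in lavage naive T cells. In the Th2 lymph node library this region was made of separate peaks of 331.9 and 407.7 tags. The Il4 region had 495 and 551.8 tags in Th2 cells, 478.6 and 507.7 in ILC2s and 187.7 in lavage naive T cells. Neither region had a peak in lymph node naive T cells. The Rad50 region that also spans the Il5 gene (53702242 to 53725276) reached 1978.3 and 2223.8 tags in ILC2s as 1 stitched peak, with separate peaks of 433.9, 73.6 and 364.0 in lavage Th2 cells and 550.9, 53.9 and 267.0 in lymph node Th2 cells, and 229.5 and 251.5 in naive T cells.

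**Figure D4:**
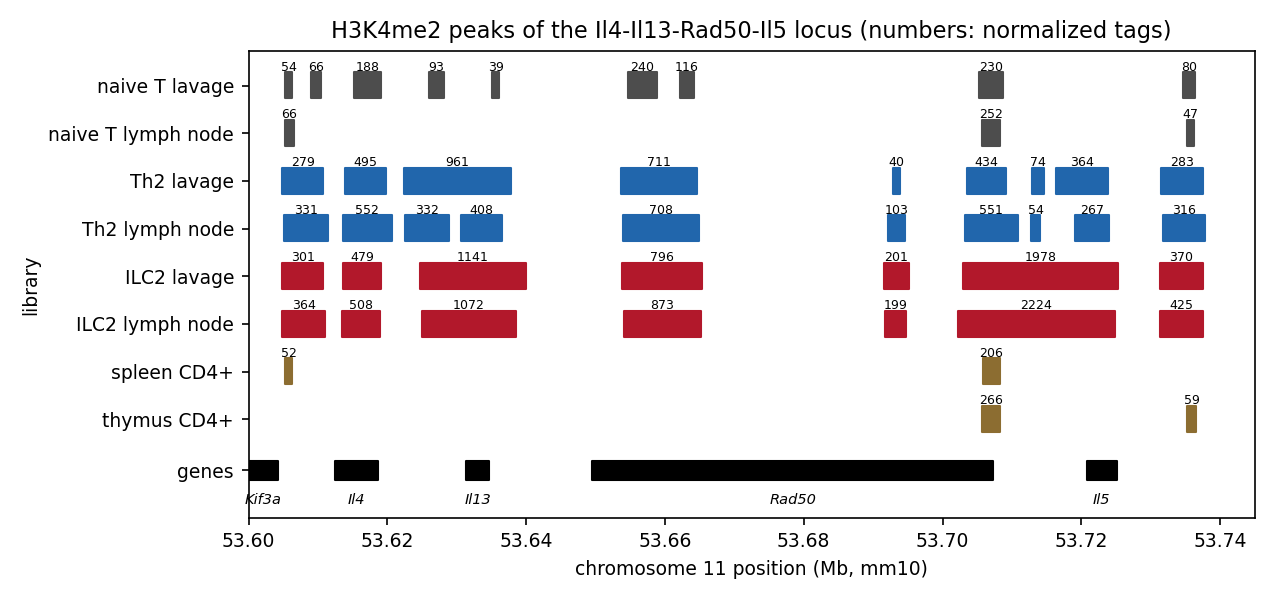
Peaks of the 8 libraries along chromosome 11 across Il4, Il13, Rad50 and Il5 (mm10), drawn to scale with the normalized tag count above each peak and gene intervals in black. Both ILC2 libraries have 1 peak across the end of Rad50 and the whole of Il5, of 1978.3 and 2223.8 tags, where the Th2 libraries have separate peaks.

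Relative to matched lists, T cell gene lists leaned to Th2 cells in the comparison with ILC2s, and no list leaned to ILC2s past the threshold. Themis, Ctla4, Ets1 and Slamf1 each had 3 regions called only in Th2 cells, and Foxp1 had a difference of -7. Cd40lg, Cd6, Cd2, Izumo1r and Il21, which encodes a follicular helper cytokine, had 2 each. On the ILC2 side Tiam1 had 12 regions, Rora 11, Pde7b 10, Bcl2 8, Kit 7, Tox 4 and Arg1 3. Il6 and Csf2 had 3 each and Il9 had 2.

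T cell receptor and identity genes had 3 regions only in ILC2s and 14 only in Th2 cells among 61, a balance of -18.0% against 18.6% in matched lists (adjusted p = 0.0038 by permutation of lists). Naive and central T cell genes had 6 and 12 of 149, regulatory T cell genes 2 and 6 of 40, and follicular helper genes 0 and 3 of 28 (adjusted p = 0.033 for each). The naive and central call was lost without the lavage ILC2 library (adjusted p = 0.056) and the regulatory T cell call without the lymph node ILC2 library (0.06). Type 2 cytokine genes had 11 and 1 of 31, which did not pass (adjusted p = 0.39) since regions of matched lists also leaned to ILC2s, nor did the ILC2 identity list with 36 and 1 of 111 (adjusted p = 0.24). In all, 5442 regions were called only in ILC2s and 423 only in Th2 cells, where other splits gave at most 63 (194 with equal numbers by score, and 667 with the upper part of each list by score, where the Th2 side had 717). With equal numbers of peaks by normalized tag count there were 1563 and 1340, the ILC2 share moving from 92.8% to 53.8%, and without the Th2 lavage library the Th2 side came to 737.

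At common regions, 253 peaks were higher in ILC2s and 185 higher in Th2 cells (limma). Without centring the counts were 710 and 136, so that the ILC2 share moved from 57.8% to 83.9%, and with the replicate block they were 131 and 121. Chdh (2.93), Ikzf1 (2.87), Mgat5 (2.89), Gm5148 (2.20) and Notch2 (2.73) were higher in ILC2s, and Cd3d (-3.40), Cd3e (-3.35), Thy1 (-2.76) and the region 261 kb from Gata3 (-3.93) in Th2 cells, all at a limma adjusted p of 0.0038 or less. With tags per kb the counts were 11 and 13, and Ikzf1 had -0.10. Gata3 itself did not differ by this test (0.18, SE 0.21, limma adjusted p = 0.66), nor did the region beside Il5 (-0.02, SE 0.38, limma adjusted p = 0.98). Among T cell receptor and identity regions, 9 of 21 were lower in ILC2s over all regions and 10 adjusted over the list alone. Of naive and central T cell regions, 3 of 41 were lower over all regions and 14 adjusted over the list alone. The calls were lost with any of these 4 libraries left out, and rose with either naive T library left out. The naive T pair enters the shared spread, so these limma p-values also depend on libraries outside the comparison.

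Of regions by cell type pattern, 2748 were called in ILC2s alone, 470 in naive T cells alone and 49 in Th2 cells alone. ILC2s and Th2 cells shared 233 regions without naive T cells, against 955 shared by ILC2s and naive T cells without Th2 cells and 224 shared by both T cell types without ILC2s. The 955 were 124 with equal numbers of peaks by normalized tag count, and were 2502 without the lavage naive T library and 1499 without the lavage Th2 library. The 233 were 748 without the lavage naive T library and 371 without the lavage Th2 library, and the 224 were 352 without the lymph node naive T library and 540 with equal numbers by normalized tag count. The tallest of the 224 T cell regions lay at Cd247, Themis, Cd40lg, Cd6 and Cd4, and were chosen after their values were seen. Cd247, which encodes a signalling chain of the T cell receptor, led with a mean of 2084.1 tags over the 4 T cell libraries.

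Few regions were called in every library of one site and none of the other. There were 18 regions called in all 3 lavage and no lymph node library, with genes such as Bhlhe40, Klf6, Dusp4 and Ikzf2 nearby, and 10 showed the reverse, with Tnfaip3, Cd200 and Ctse among the nearest genes. The peaks near these genes were low, with 39.9 to 101.1 tags in the lavage and 41.3 to 81.3 in the lymph node. The tag minimum was 39.9 to 40.4, so a missing call beside them can be a small difference around it. Limma called 0 regions by site, with 525 at an unadjusted p under 0.05. Tbx21, the Th1 master regulator gene, had the larger value in the lavage in each cell type, with 662.9 against 227.1 tags in naive T cells, 416.4 against 41.3 in Th2 cells and 86.6 against 39.0 in ILC2s (log2 difference 2.17, SE 0.42, limma adjusted p = 0.89). The lymph node values of Th2 cells and ILC2s lay at the tag minimum. With 1 library left out the regions numbered between 37 and 151 for the lavage (151 without the lymph node ILC2 library) and between 14 and 245 for the lymph node (245 without the lymph node Th2 library), where fewer libraries had to match.

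Regions called only in naive T cells mostly had a spleen peak, and regions absent from naive T cells mostly had none. The selection largely set this outcome, since the naive T library of the lymph node had a Jaccard index of 0.845 with the spleen library. Of the 3222 ILC2 regions absent from naive T cells, 1.6% had a spleen CD4+ peak within 500 bp (exact 95% interval 1.2% to 2.1%) and 7.3% a thymus CD4+ peak (6.4% to 8.2%). Of the 817 naive T regions absent from ILC2s, 94.1% had a spleen peak (92.3% to 95.6%) and 59.5% a thymus peak (56.0% to 62.9%). Of the 307 Th2 regions absent from naive T cells, 0.3% had a spleen peak (0.0% to 1.8%) and 6.2% a thymus peak (3.8% to 9.5%), against 95.5% and 76.2% of the 1592 naive T regions absent from Th2 cells. Between ILC2s and Th2 cells the shares lay closer: a spleen peak at 42.3% of the 5442 ILC2 regions (41.0% to 43.6%) and 54.4% of the 423 Th2 regions (49.5% to 59.2%), and a thymus peak at 39.3% (38.0% to 40.7%) and 33.3% (28.9% to 38.0%). Regions called in all 6 libraries had a spleen peak in 99.4%, and 11084 of those 11669 had a thymus peak. These intervals cover counting error over regions in 1 library of each organ.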

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

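Merging distance, pseudocount, quantile normalization, the 1 bp overlap and the other similarity measure moved no count of regions or of passing lists by over 1.5 times. Single results did change, among them these: the ILC2 identity list against naive T had an adjusted p of 0.086 when peaks were merged by a 1 bp overlap, the Th17 and ILC3 list passed with merging within 1000 bp (0.038), and Il5 in Th2 cells against naive T passed with quantile normalization (limma adjusted p 0.036). The motif alternatives were not run, with no genome sequence used here. Equal numbers by normalized tag count or tags per kb, and heights as tags per kb, were chosen after the data were seen. Where an alternative below changed a result the cause was not tested, except that equal list lengths force the 2 sides of a comparison together and that dropping a library leaves fewer that must match. Of 164 comparisons of a region count or similarity with an alternative, 107 stayed within 1.5 times or within the spread, 56 moved and 1 reversed. Of 812 for gene lists, 735 kept direction and side of the threshold, 56 fell below it, 14 passed it and 1 reversed, and in 6 the number of passing lists moved by over 1.5 times. Of 811 for heights of named regions, 623 kept both, 115 fell below the threshold, 17 passed it, 5 reversed, and 51 that had not passed changed sign. Of 1582 for regions near named genes, 1174 were level with the reported value, 403 moved and 5 reversed. Depth limits what a missing peak shows most in the Th2 libraries, which had the fewest tags. With 1 library dropped, the lone one is assumed to vary like the other groups.

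With equal numbers by score, only-regions were 1984 ILC2 against naive T, 838 and 894 for Th2 and naive T, 2353 and 1490 for ILC2 and Th2; shared pairs 364, 289 and 673 (lacking naive T, Th2 and ILC2); lavage 66, lymph node 32; 1 list test passed; Klf13 and S1pr1 (Th2 against naive T) turned to 1 each. With the upper part of each list by score, they were 1921 ILC2 against naive T, 751 Th2 against naive T, 2344 and 717 for ILC2 and Th2, 372 lacking Th2, 162 lavage, 134 lymph node; 0 list tests passed, the follicular helper list (ILC2 against naive T) turned to an excess of 3.0% over matched lists and Cxcr5 to 1. By normalized tag count they were 1529 ILC2 against naive T, 636 and 522, 1563 and 1340; 124 lacking Th2 and 540 lacking ILC2; 5 list tests; Prdm1 (ILC2 against Th2) turned to -1. By tags per kb they were 1622, then 672 and 560, then 1577 and 1342; 129 and 535; lavage 34; 6 list tests. Nearest genes within 10 kb left 3.

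Heights as tags per kb gave 53 higher and 23 lower for ILC2 against naive T, 0 for Th2 against naive T, 11 and 13 for ILC2 against Th2; Ikzf1 turned to -0.10 and Rora (start 69027804) to -0.11 against Th2 and -0.08 against naive T, Rhbdf2 to -0.19 and 4932438H23Rik to -0.04. Besides these 5 reversals, 16 results for named regions fell below the threshold with tags per kb, and 34 kept direction and side. Without centring, Th2 against naive T gave 32 and 220, ILC2 against Th2 710 higher. Sums of peaks, and regions above the median height, gave 1 lower for Th2 against naive T.

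Numbers of replicates stand for the site, and the labels do not say whether animals were shared; deviations of same-numbered libraries correlated at 0.11, -0.02 and 0.24 across regions. With the replicate block, Th2 against naive T gave 0 calls, ILC2 against Th2 131 and 121, ILC2 against naive T 282 and 166.

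Leaving out each library in turn gave these ranges: ILC2 against naive T 3222 to 5039 and 817 to 4984; Th2 against naive T 307 to 992 and 1592 to 7757; Th2-only against ILC2 423 to 737; regions lacking naive T 240 to 748, lacking Th2 1034 to 2502, lacking ILC2 246 to 352; lavage 37 to 151, lymph node 14 to 245; list tests 7 to 15; similarity by cell type 0.094 to 0.249 and by site -0.083 to 0.004, positive without the Th2 lymph node library; Foxp1 near Th2 against naive T -7 to 5. Height ranges were 0 to 1404 and 0 to 708 (ILC2 against naive T), 0 to 1673 and 0 to 1052 (Th2 against naive T), 0 to 841 and 0 to 840 (ILC2 against Th2).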

Other observations

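Of the tests in this part, that of list length was set before its result was seen and the others after. The naive T libraries differed from each other at genes of the resting state. The lymph node library alone of the pair had 6541 regions and the lavage library alone 1537. Tcf7, Lef1 and Ccr7, genes of resting and recirculating T cells chosen here after their values were seen, had taller peaks in the lymph node; the Tcf7 region held 3964.3 tags there and 625.7 in the lavage, and the Ccr7 region at 99141962 held 2260 and 399.6. As a description of these 2 libraries, with no replicate, the balance of lavage over lymph node regions lay at percentile 0.1 of matched random lists for naive and central T cell genes, at 99.8 for type 2 cytokines and at 81.8 for Th1 and cytotoxic genes. Lists of other cells moved as far, with Th17 and ILC3 genes and eosinophil and mast cell genes (3 regions against 0) at 99.8, ILC2 identity at 99.6, locus neighbours and activation genes at 98.5 and airway epithelium at 2.8. Th2 identity genes had 13 regions in the lavage library alone of the pair and 0 in the lymph node library alone. Regions of the lavage library missing from the other 3 T cell libraries were tallest at Ifng, the interferon gamma gene, with 319.7 tags, and Cd80, with 263.3, both chosen after their values were seen.

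The lavage naive T library shared more covered bases with Th2 cells than with lymph node naive T cells. Equally long lists argue against list length as the whole cause, since they left the Jaccard index 0.096 higher with Th2 cells (0.75 and 0.714 against 0.636). Of the 992 regions that both Th2 libraries had and lymph node naive T cells lacked, the library called 685 (69.1%, exact 95% interval 66.1% to 71.9%). Of the regions that 1 Th2 library had and lymph node naive T cells lacked, the other Th2 library called 71.3% and 71.5%. The first share starts from regions called in both Th2 libraries and the others from regions called in 1, so no match can be read from them. Near type 2 and Th2 list genes there were 31 of the 992 regions, where Th2 lavage over Th2 lymph node was 1.04 (quartiles 0.88 and 1.4). The lavage naive T library called 19 of the 31. Its height over the Th2 mean there was 0.46 of that ratio at regions called in all 6 libraries (quartiles 0.27 and 0.67), against 0.82 (0.59 and 1.1) at the other 666 regions it called. At list regions chosen alike for the 3 libraries it was the lowest in 28 of 31 (90.3%, exact 95% interval 74.2% to 98.0%, counting error only), against 1 and 2 for the Th2 libraries, and outside the lists in 665 of 1247, against 139 and 443, which argues against a Th2 library as the whole content of this sample. Site stays open, with a between-site Jaccard index of 0.613 in naive T cells against 0.782 and 0.834 in Th2 cells and ILC2s. With 1 naive T library per site it cannot be parted from a difference in sorted cells or in the libraries themselves. The headers gave a fragment length of 108 bp for lavage and 182 bp for lymph node naive T cells, and 180 bp for spleen CD4+ cells. The Th2 pair, with 182 and 116 bp, differed in length too.

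A mixture of Th2 cells with naive T cells of the lymph node kind was tested on the lavage naive T library's own regions. Regions of at least 100 tags called in this library alone of the 4 T cell libraries numbered 45, against 5 and 24 for the Th2 libraries. Excluding a mixture needed over 3 times as many as either Th2 library had, which held against the lavage Th2 library and not against that of the lymph node, so a mixture cannot be told apart from other sources of these regions.

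Cd3e and Cd3d were called in both ILC2 libraries at low height, and T cells among the ILC2s, which flow cytometric sorting is meant to remove, may be their source. This stays open, because the tables do not fix the share of T cells. The test took regions called in all 4 T cell libraries and in neither ILC2 library. At the share given by peak densities, 44.4%, 4 of them, at Themis, Cd4, Tuba3a and an intergenic site on chromosome 15, would exceed the threshold of 40.1 tags per kb. Their absence from ILC2s was set by the selection, and T cell regions above the threshold that ILC2s did have were not counted. Few ILC2 peaks were called below the threshold density (4.4% and 4.3% in the 2 libraries), so the density of a low peak may overstate that share by an unknown amount. At the 10.4% to 11.1% given by tag counts 0 such regions would exceed it.

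For the comparison of sites, 7 of the 10 splits of the 6 libraries into 3 and 3 gave at least the 28 differing regions of the real split, and the highest other gave 1675. In peak height the real split called 0 regions, which any split reaches, so setting it beside the other splits shows nothing about the site. The highest other split called 861. These splits are too few for a share under 0.05. Among the 4 splits with 1 library of each cell type on either side, the real one had the most regions, with 28 against 14, 10 and 10. The split with the most regions set lavage naive T cells with Th2 cells against lymph node naive T cells with ILC2s, and its calls in height, 861, are those of a fit that with the cell type term compares only the lavage naive T library with that of the lymph node. This points to a structure of the samples in the naive T pair, already seen in their Jaccard index.

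The list called in Th2 cells alone held a mitochondrial region, the tallest of the 49 with 67.3 tags in the lavage and 471.7 in the lymph node (mean 269.5), chosen after its value was seen.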
